A study of Mus musculus with 49 samples.

How the data were processed

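Livers of male C57BL6/N mice were profiled on Affymetrix mouse genome arrays after 1 intraperitoneal dose of 300 mg/kg acetaminophen (APAP, paracetamol), a drug whose overdose injures the hepatocytes around the central vein. Per the labels' protocols, total RNA was isolated with TRIzol, transcribed from oligo(dT) primers and labelled with biotin. The series' design text states that mice were starved overnight before the dose and fed freely afterwards. It lists times up to 8 d, and the 16 d group is known from the labels alone. Neither the design text nor the labels say whether the control mice were starved or received the vehicle. The 49 arrays fall into 10 groups by their titles and treatment labels: untreated control and 1 h, 6 h, 12 h, 1 d, 2 d, 4 d, 6 d, 8 d and 16 d after the dose, with 4 arrays at 6 h and 5 in every other group. The labels number the arrays of a group as replicates without saying that each is a separate mouse, so all p-values measure only the spread between these arrays, which may in part be technical.

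Per the submitters' processing notes, the values were made with the oligo package (version 1.52.0) and robust multi-array averaging (RMA), which corrects background, quantile normalizes and summarises the probes of a probe set. The deposited table gives 1 log2 expression value per probe set and array, and the range of these values is that of RMA output on a log2 scale. Whether all arrays were normalized in a single run is not given in the sources used here. In the table used here, the 25 arrays of 1 h, 12 h, 1 d, 2 d and 16 d held a value for all 45101 probe sets. The 24 arrays of the control, 6 h, 4 d, 6 d and 8 d groups held values for the first 8137 or 8138 only. Comparisons with control therefore cover the 8137 probe sets with a value on all arrays. The platform annotation gave a single gene symbol for 7370 of them, several symbols for 223 and no listing for 544. The probe set with the highest mean over all arrays stood for its gene, which left 5976 genes. For the 25 complete arrays, 34958 probe sets had a single symbol, 932 had several and 9211 were not listed, which left 18194 genes. This larger set was compared with the 1 h group as reference, since the control arrays could not be used there. That set of comparisons was added after the data were seen. Values were taken as deposited, without further normalization or filtering of dim genes. An array has no sequencing depth, and the number of arrays limits the precision, together with background and saturation of the probe sets. The lowest 10% of gene values lay under 3.38 and the highest value was 14.34, and differences from levels near either end can be understated.

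Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with default settings) in a model with 1 mean per group over all arrays, so that the groups shared 1 estimate of the spread. The replicate numbers did not enter this model. Contrasts were each time against control, each time against the time before, and the moderated F test over the 9 contrasts with control. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes of the contrast, and the number of called genes with a log2 difference of at least 1 (2-fold) is given beside it. The grouping, the tests, the gene lists and the rule for naming genes were fixed before the data were examined. The 47 gene lists were drawn from general knowledge of liver injury, stress, inflammation, cell division, metabolism, hepatic cell types and neighbouring tissues. Some genes belong to several lists, such as Mt1 and Mt2 (acute phase and glucocorticoid) and Fgf21 (ATF4 and fasting). Each list with at least 3 measured members was tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over all lists and times of a table. The p obtained with a correlation estimated from the data is given beside each list described, because most list calls were lost with it. Members of a list are counted as higher or lower over all genes tested and, separately, adjusted over the list alone.

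The named genes follow a fixed rule. At each time they are the 5 largest rises and 5 largest falls among called genes whose arrays all lie above, or all below, every control array. To these are added, for the 6 lists with the smallest camera p, the 3 called members that moved most in the list's direction. Between neighbouring times the 3 largest rises and falls are taken by the same criteria. A panel of 40 genes followed through all times completes the rule, as far as its members were measured. Where other probe sets of a named gene moved the opposite way at an adjusted p under 0.05 this was to be said, and no such case occurred.

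Alternatives fixed in advance were the mean of all probe sets of a gene, leaving out probe sets whose names mark possible cross-hybridisation, leaving out dim genes, an eBayes fit with trend and robust estimation, array weights, centring each array on its cytosolic ribosomal protein genes, fitting only the groups compared, the replicate number as a block, the estimated inter-gene correlation, and leaving out each array in turn. Added after the data were seen were quantile normalization of the deposited values, the fit without 3 arrays of narrow value range, and the fit without control replicate 2 and 8 d replicate 2, which shared a deviation (residual correlation 0.588). Other splits of the arrays of each contrast were drawn 100 times. A planned test of 3' to 5' control probe sets against the control group was not run, since the control arrays of the table used here end before those probe sets, and the test was made against 1 h instead.

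The model was tested on simulated data with 200 genes shifted by known amounts. In the simulated contrast of 2 d with control over 5976 genes, 44 of 67 genes shifted by 0.5 on the log2 scale were recovered, 67 of 67 shifted by 1 and 66 of 66 shifted by 2, with 10 false calls. For 2 d against 1 h over 18194 genes the numbers were 28 of 67, 56 of 67 and 66 of 66, with 12 false calls. The simulated noise was independent between genes and, for each gene, equally wide on all arrays. The real arrays include some of narrow range with shared deviations, so the false calls in the real data may be more numerous. Within groups, correlations between arrays lay between 0.969 and 0.996, and no pair of arrays held more than 18 probe sets with equal values, so every array was counted as 1 sample.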

Results

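The data are log2 expression values of mouse liver from a control group and 9 times after a single toxic dose of acetaminophen, from 1 h to 16 d. Each group had 5 arrays, except 6 h with 4. The comparisons ask which transcripts moved away from control at each time, and how neighbouring times differed. Changes are log2 differences between group means ± the standard error (SE) of limma's fit, and group levels are log2 means ± SD. Over the shared probe sets the array means lay between 6.03 and 6.33. The SD of the values within an array was 2.40 to 2.48 on 46 arrays and 2.25, 2.26 and 2.26 on control replicate 3, 1 h replicate 3 and 16 d replicate 4.

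One hour after the dose, immediate early transcription factors and the hepatocyte genes Igfbp1 and G6pc were higher than in control livers, and some transcription factor genes were lower. Egr1 and Fos, transcription factors switched on within minutes of many stimuli, rose by 4.88 ± 0.56 and 4.81 ± 0.58. Igfbp1, a secreted binding protein of insulin-like growth factors that fasting and stress induce, went from 7.07 ± 0.97 (SD, n = 5) to 12.01 ± 0.54 (SD, n = 5), a rise of 4.94 ± 0.49 with an adjusted p = 3.73e-09 in limma. Foxa1 and Onecut1, transcription factors of hepatocyte identity, changed by −2.39 ± 0.24 and −3.64 ± 0.54, and Id3, an inhibitor of basic helix-loop-helix factors, by −1.96 ± 0.32.

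Of 14 immediate early genes measured, 5 rose and 0 fell at 1 h (7 and 0 adjusted over the list alone), with a list test at adjusted p = 4.4e-14 and adjusted p = 0.0294 with an estimated correlation. Among 5 gluconeogenesis genes 2 rose (also 2 adjusted over the list alone), Igfbp1 and G6pc, the catalytic subunit of glucose-6-phosphatase, by 2.32 ± 0.42. That list had an adjusted p = 1.55e-08, and adjusted p = 0.00033 with an estimated correlation. Glucocorticoid-responsive genes gave the same pair of calls, at adjusted p = 2.53e-09 and adjusted p = 0.00033 with an estimated correlation, although of 8 members only Zbtb16 rose over all genes (1.76 ± 0.36), against 6 adjusted over the list alone. In the fit of the compared groups alone Zbtb16 had an adjusted p = 0.0682. The other 4 called lists had medians from −0.46 to −0.10, no member past the test over all genes, and adjusted p = 0.446 to 0.664 with an estimated correlation. Cyp2e1, the cytochrome P450 that forms the reactive metabolite of acetaminophen, differed by 0.01 from control at 1 h (adjusted p = 0.996), but at 13.72 in control its signal lay near the top of the range, so that no stability can be read from it.

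Over all 5976 genes limma called 38 at 1 h, 20 higher and 18 lower, of which 14 and 11 changed at least 2-fold. The count was 79 without control replicate 3, one of the narrow arrays, and 131 with array weights.

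At 6 h immediate early genes and p53 targets were higher than in control, and pericentral metabolism genes were lower. Fos had risen by 6.03 ± 0.61 and Egr1 by 5.85 ± 0.59. Btg2, an antiproliferative gene, rose by 5.01 ± 0.65 and Maff, a small Maf transcription factor, by 4.79 ± 0.35. Fgf21, a hormone that hepatocytes release on fasting and cell stress, rose by 4.42 ± 0.55 (adjusted p = 1.68e-07), with levels of 10.47 ± 2.00 (SD, n = 4) against 6.05 ± 0.21 (SD, n = 5). Cxcl1, a chemokine that draws neutrophils, rose by 4.07 ± 0.72 and Cdkn1a, the cell cycle inhibitor p21, by 2.93 ± 0.43. The cytokine and chemokine list was not called (2 of 14 higher and 0 lower, also adjusted over the list alone; adjusted p = 0.084, and adjusted p = 0.596 with an estimated correlation). Foxa1 and Foxa2 changed by −2.03 ± 0.26 and −2.13 ± 0.29.

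Of the 14 immediate early genes, 9 rose and 0 fell at 6 h (11 and 0 adjusted over the list alone; list test adjusted p = 1.59e-23, and adjusted p = 0.00756 with an estimated correlation). Among 10 p53 targets 5 rose and 1 fell, the same numbers as adjusted over the list alone (adjusted p = 1.66e-05, and adjusted p = 0.0171 with an estimated correlation), with Trp53inp1 up by 1.48 ± 0.29. Btg2 belongs to both the p53 and the immediate early list, so these list calls are not independent. Glucocorticoid-responsive genes had 5 of 8 members higher and 1 lower (6 and 1 adjusted over the list alone), including Sgk1 at 2.36 ± 0.26 and the metallothionein Mt1 at 2.71 ± 0.63. Their list test gave an adjusted p = 6.58e-06, and adjusted p = 0.00756 with an estimated correlation. Pericentral hepatocyte genes moved down in 4 of 9 cases and up in 0 (6 and 0 adjusted over the list alone). Oat, ornithine aminotransferase, changed by −1.76 ± 0.34 (−1.17 without 6 h replicate 5), and the ammonium transporter Rhbg by −1.38 ± 0.22. The list had an adjusted p = 6.23e-07, and adjusted p = 0.0573 with an estimated correlation. Cytoskeleton and annexin genes had 4 of 13 members higher and 0 lower (5 and 0 adjusted over the list alone), among them the tubulin Tubb6 (2.06 ± 0.37) and the keratin Krt8 (1.40 ± 0.22), at an adjusted p = 0.000224 and adjusted p = 0.332 with an estimated correlation. Srxn1 and Txnrd1, NRF2-driven antioxidant enzymes, rose by 0.79 ± 0.16 and 0.98 ± 0.16.

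The count at 6 h was 339 genes, 226 higher and 113 lower, with 111 and 30 changed at least 2-fold. After quantile normalization it was 255 higher and 301 lower, with array weights 759 genes, and without 6 h replicate 5 it was 223 genes.

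At 12 h, heat shock proteins, NRF2-driven antioxidant enzymes and cytoskeletal genes were higher, and many cytochrome P450 and bile acid genes were lower. Dnajb1, a co-chaperone of the heat shock response, rose by 3.19 ± 0.32 (adjusted p = 1.49e-10), Bag3 by 2.37 ± 0.31 and the small heat shock protein Hspb1 by 2.26 ± 0.36. Txnrd1, thioredoxin reductase, rose by 1.8 ± 0.15 from 9.72 ± 0.14 (SD, n = 5) to 11.52 ± 0.42 (SD, n = 5), Srxn1 by 1.75 ± 0.15 and Nqo1 by 1.28 ± 0.25. Klf6 reached 4.85 ± 0.52 above control and Maff 4.95 ± 0.33 (adjusted p = 3.78e-15). S100a8, an abundant neutrophil protein, rose by 4.32 ± 0.63 and Ccl2, a monocyte chemoattractant, by 1.28. Cyp2c37, Cyp7a1, the rate-limiting enzyme of bile acid synthesis, and the amine methyltransferase Inmt changed by −2.84 ± 0.38, −3.14 ± 0.65 and −2.78 ± 0.47. Cyp2e1 fell by 0.37 ± 0.11 (adjusted p = 0.01), and Fgf21 was at −0.22, which was not called.

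Heat shock genes rose in 7 of 8 cases at 12 h and fell in 0, as many as adjusted over the list alone (adjusted p = 2.38e-07, and adjusted p = 0.125 with an estimated correlation). NRF2 targets counted 7 of 12 higher and 1 lower, the same adjusted over the list alone (adjusted p = 2.87e-07, and adjusted p = 0.0474 with an estimated correlation). Of 13 cytoskeleton and annexin genes 11 rose and 0 fell, again the same adjusted over the list alone (adjusted p = 1.52e-11, and adjusted p = 0.0294 with an estimated correlation), with Tubb6 at 3.70 ± 0.35 and Krt8 at 2.12 ± 0.21. Against 1 h over all probe sets, Tubb6 was at 3.75 at 12 h, and at 1.83 as the mean of its probe sets. Ribosome biogenesis genes had 5 of 11 members higher and 0 lower, also adjusted over the list alone, among them Gar1 (1.22) and nucleolin, Ncl (0.88), with adjusted p = 2.06e-05 and adjusted p = 0.214 with an estimated correlation. Drug-metabolising cytochromes P450 moved down in 10 of 16 cases and up in 2 (11 and 2 adjusted over the list alone; adjusted p = 0.00121, and adjusted p = 0.22 with an estimated correlation). Bile acid genes moved down in 5 of 9 cases and up in 0, the same adjusted over the list alone (adjusted p = 0.00507, and adjusted p = 0.335 with an estimated correlation).

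In total 1419 genes were called at 12 h, 688 higher and 731 lower, and 223 and 96 of them changed at least 2-fold. Centring on ribosomal protein genes shifted the median of all genes by −0.14 and gave 513 higher and 1599 lower, and the fit of the compared groups alone called 805 genes.

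One day after the dose, cytoskeletal and macrophage genes were higher than in control, and cytochromes P450, bile acid and male-biased liver genes were lower. Chil3, a chitinase-like protein of activated macrophages, rose by 5.86 ± 0.46 (adjusted p = 3.56e-13), from 3.37 ± 0.19 (SD, n = 5) to 9.23 ± 0.81 (SD, n = 5), and its control level lies among the lowest 10% of values, near background. S100a8 was 4.63 ± 0.63 and Cxcl1 4.77 ± 0.68 above control. The membrane-binding protein Anxa2 and the calcium-binding protein S100a6 rose by 3.93 ± 0.30 and 4.18 ± 0.45. Against 1 h over all probe sets, Anxa2 was at 4.00 at 1 d, and at 1.68 as the mean of its probe sets. Cyp7a1 stood at −4.94 ± 0.65 (adjusted p = 8.16e-08), Cyp2c37 at −4.04 ± 0.38, Oat at −3.71 ± 0.32 and Inmt at −3.80 ± 0.47. Cyp2e1 fell by 0.87 ± 0.11.

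All 13 cytoskeleton and annexin genes rose at 1 d, also adjusted over the list alone (adjusted p = 7.2e-17, and adjusted p = 0.0106 with an estimated correlation). Of 9 pericentral hepatocyte genes 7 fell and 0 rose, the same adjusted over the list alone (adjusted p = 1.59e-07, and adjusted p = 0.0469 with an estimated correlation), among them Prodh, proline dehydrogenase, at −2.0 ± 0.24. Cytochromes P450 counted 11 of 16 lower and 1 higher, again the same adjusted over the list alone (adjusted p = 8.73e-07, and adjusted p = 0.0364 with an estimated correlation), with Cyp2c50 at −2.70 ± 0.31 and Cyp2c29 at −2.13 ± 0.37. Monocyte and macrophage markers rose in 7 of 11 cases and fell in 0, also adjusted over the list alone (adjusted p = 0.000278, and adjusted p = 0.345 with an estimated correlation). Bile acid genes fell in 6 of 9 cases and rose in 0, the same adjusted over the list alone (adjusted p = 6.66e-05, and adjusted p = 0.125 with an estimated correlation). The cytokine and chemokine list was not called at 1 d (5 higher and 1 lower of 14, and 7 and 2 adjusted over the list alone; adjusted p = 0.0806, and adjusted p = 0.596 with an estimated correlation). Male-biased liver genes fell in 6 of 6 cases, also adjusted over the list alone (adjusted p = 5.22e-05, and adjusted p = 0.0797 with an estimated correlation). Hsd3b5, a steroid dehydrogenase, was at −3.33 ± 0.67 and the organic anion transporter Slco1a1 at −2.77 ± 0.36. Cholesterol synthesis genes rose in 9 of 10 cases and fell in 0, the same adjusted over the list alone (adjusted p = 4.96e-06, and adjusted p = 0.311 with an estimated correlation), with Fdps, farnesyl diphosphate synthase, at 2.65 ± 0.38. Hypoxia and glycolysis genes rose in 10 of 12 cases and fell in 1, also adjusted over the list alone (adjusted p = 0.000116, and adjusted p = 0.255 with an estimated correlation). Oxidative phosphorylation genes fell in 10 of 13 cases and rose in 0 (11 and 0 adjusted over the list alone), with adjusted p = 8.97e-05 and adjusted p = 0.311 with an estimated correlation.

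The count at 1 d was 1772 genes, 969 higher and 803 lower, with 284 and 132 changed at least 2-fold. Ribosomal centring shifted the median of all genes by −0.30 here and gave 521 higher and 3096 lower, and the fit of the compared groups alone called 1135 genes.

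At 2 d DNA replication, mitosis, fibrillar matrix and macrophage genes were higher than in control. Mcm6, a subunit of the replicative helicase, rose by 4.15 ± 0.30 (adjusted p = 8.42e-15) and Mcm5 by 3.33 ± 0.28. Nusap1 and Cdc20, which act in mitosis, rose by 2.90 ± 0.33 and 2.88 ± 0.42, with 1.41 for Nusap1 as the mean of its probe sets. Col1a2, a chain of type I collagen, rose by 4.25 ± 0.26 and Acta2, the smooth muscle actin of myofibroblasts, by 3.95 ± 0.24 from 5.86 ± 0.39 (SD, n = 5) to 9.81 ± 0.30 (SD, n = 5). The Acta2 value comes from a probe set marked for possible cross-hybridisation, and the gene's unmarked probe set gave −0.013 at 2 d against 1 h. S100a6 reached 6.68 ± 0.45 and Anxa2 5.08 ± 0.30 above control (adjusted p = 1.03e-15 and 2.36e-17). Against 1 h over all probe sets, Anxa2 was at 5.15 at 2 d, and at 2.07 as the mean of its probe sets. Ccl2 rose by 2.92 ± 0.35. Afp, alpha-fetoprotein, rose by 2.97 ± 0.32. Cyp2c29 and Cyp2c37 were at −2.98 ± 0.37 and −3.24 ± 0.38, and Cyp2e1 fell by 1.00 ± 0.11. Scd1, stearoyl-CoA desaturase, was at −2.75 ± 0.27.

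DNA replication genes rose in 19 of 19 cases at 2 d, also adjusted over the list alone (adjusted p = 1.75e-19, and adjusted p = 0.0189 with an estimated correlation). Mitosis genes rose in 7 of 8 cases and fell in 0, the same adjusted over the list alone (adjusted p = 3.66e-07, and adjusted p = 0.0925 with an estimated correlation). Fibrillar matrix and myofibroblast genes counted 13 of 14 higher and 1 lower, Mmp2 (a gelatinase), also adjusted over the list alone (adjusted p = 1.26e-14, and adjusted p = 0.0116 with an estimated correlation). Tagln, a partner of smooth muscle actin, was at 3.65 ± 0.27. Monocyte and macrophage markers rose in 11 of 11 cases, as many as adjusted over the list alone (adjusted p = 2.97e-08, and adjusted p = 0.0906 with an estimated correlation), with Lyz2 at 2.33 ± 0.29 and Ccr2 at 2.12 ± 0.22. Lipid-associated macrophage markers rose in 5 of 5 cases, again the same adjusted over the list alone (adjusted p = 7.67e-06, and adjusted p = 0.0197 with an estimated correlation). Among them Lpl, lipoprotein lipase, rose by 2.58 ± 0.24 and Trem2, a lipid-sensing receptor, by 1.36 ± 0.12. For Trem2 the unmarked probe set gave −0.0052, and the mean of its probe sets 0.68. Cytoskeleton and annexin genes rose in 13 of 13 cases, also adjusted over the list alone (adjusted p = 1.86e-17, and adjusted p = 0.00971 with an estimated correlation).

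Limma called 1948 genes at 2 d, 1189 higher and 759 lower, of which 422 and 69 changed at least 2-fold. Ribosomal centring, with a median shift of −0.27, gave 742 higher and 2804 lower, and quantile normalization gave 1012 higher and 1463 lower.

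At 4 d, lipid synthesis, DNA replication, matrix and lipid-associated macrophage genes were higher than in control. Thrsp, a lipogenic regulator, rose by 5.76 ± 0.47 from 6.80 ± 0.86 (SD, n = 5) to 12.56 ± 0.31 (SD, n = 5). Fasn, fatty acid synthase, rose by 3.67 ± 0.29 (adjusted p = 2.45e-12), Acss2, acetyl-CoA synthetase, by 2.91 ± 0.26, and Scd1, which had been low at 2 d, stood 0.96 ± 0.27 above control. The Scd1 probe set lay near the top of the signal range at 4 d (13.76 ± 0.07), and the mean of the gene's probe sets gave 2.29. Fdps and Idi1 of the sterol pathway rose by 3.93 ± 0.38 and 3.53. Mcm6 was 2.78 and cyclin A2, Ccna2, 2.23 above control. Cyp4a14, a fatty acid hydroxylase under PPAR alpha, and Vnn1, pantetheinase, changed by −3.26 ± 0.54 and −3.37 ± 0.44. Cyp2e1 (−0.24, adjusted p = 0.142, near the top of the signal range), Acta2 (0.40, adjusted p = 0.292) and Ccl2 (−0.05) were not called at 4 d.

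Cholesterol synthesis genes rose in 9 of 10 cases at 4 d and fell in 0, the same adjusted over the list alone (adjusted p = 8.92e-17, and adjusted p = 0.0294 with an estimated correlation). Fatty acid synthesis genes counted 9 of 14 higher and 1 lower (11 and 1 adjusted over the list alone; adjusted p = 2.38e-10, and adjusted p = 0.0277 with an estimated correlation). DNA replication genes were higher in 15 of 19 cases and lower in 0, also adjusted over the list alone (adjusted p = 1.66e-13, and adjusted p = 0.0544 with an estimated correlation). Fibrillar matrix genes rose in 7 of 14 cases and fell in 0 (10 and 0 adjusted over the list alone), with Lum, lumican, at 2.38 ± 0.26 and Sparc at 1.63; the list had adjusted p = 7.78e-08 and adjusted p = 0.0714 with an estimated correlation. Lipid-associated macrophage markers rose in 4 of 5 cases and fell in 0 (5 and 0 adjusted over the list alone), with adjusted p = 7.78e-08 and adjusted p = 0.00756 with an estimated correlation. Fabp5, a fatty acid binding protein, was at 2.86. Trem2 was at 1.03, but at 0.15 and not called on its unmarked probe set, and at 0.59 as the mean of its probe sets. Male-biased genes fell in 5 of 6 cases and rose in 0, the same adjusted over the list alone (adjusted p = 2.44e-05, and adjusted p = 0.0664 with an estimated correlation), among them Elovl3, a fatty acid elongase, at −3.08 ± 0.43. Proteasome subunits fell in 9 of 15 cases and rose in 0 (11 and 0 adjusted over the list alone), with adjusted p = 1.03e-06 and adjusted p = 0.311 with an estimated correlation.

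The 4 d count was 988 genes, 597 higher and 391 lower, with 192 and 40 changed at least 2-fold. Quantile normalization gave 601 higher and 749 lower, and array weights 1529 genes.

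At 6 d and 8 d cholesterol and fatty acid synthesis genes were higher than in control, and fatty acid oxidation genes were lower. Cyp4a14 was at −6.01 ± 0.54 at 6 d (adjusted p = 1.84e-10) and −5.65 ± 0.54 at 8 d, falling from 13.16 ± 0.24 (SD, n = 5) to 7.15 ± 1.48 (SD, n = 5) at 6 d. Vnn1 was at −3.72 ± 0.44 and −3.39. Acot3, a peroxisomal acyl-CoA thioesterase, was at −2.53 ± 0.52 and −2.34, and Crat, carnitine acetyltransferase, at −2.08 ± 0.29 at 6 d. Thrsp remained 4.76 ± 0.47 and 3.98 higher, Fasn 2.63 and 2.53, and Fdps 3.41 ± 0.38 and 3.33. Cxcl1 was still 5.04 ± 0.68 above control at 6 d, with 10.73 ± 1.43 (SD, n = 5) against 5.68 ± 0.74. Ifit2 and Gbp3, genes induced by interferon, rose by 1.33 ± 0.31 and 1.21 ± 0.27 at 6 d. Bcl6, a transcriptional repressor, rose by 3.92 ± 0.55 and the matricellular protein Ccn2 changed by −1.75 ± 0.37 at 8 d.

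Cholesterol synthesis genes rose in 9 of 10 cases and fell in 0 at both times, as many as adjusted over the list alone, with adjusted p = 1.2e-15 and 2.23e-18, and adjusted p = 0.032 and 0.0197 with an estimated correlation. Fatty acid synthesis genes rose in 7 and 8 of 14 cases and fell in 0 (8 and 9 higher adjusted over the list alone), with adjusted p = 2.83e-08 and 8.18e-10, and adjusted p = 0.0529 and 0.0294 with an estimated correlation. Fatty acid oxidation and fasting genes fell in 7 of 10 cases at both times and rose in 1 and 0 (7 lower and 1 and 2 higher adjusted over the list alone). Their adjusted p was 3.11e-09 and 2.41e-08, and adjusted p = 0.0883 and 0.113 with an estimated correlation. Lipid-associated macrophage markers rose in 3 of 5 cases at each time (3 and 4 adjusted over the list alone), with adjusted p = 6.58e-06 and 3.44e-06, and adjusted p = 0.0194 and 0.018 with an estimated correlation. The largest of these rises were those of Fabp5 (3.37 ± 0.41 and 3.69) and Lpl (1.68 and 1.94), which also serve fatty acid transport and uptake. Interferon-stimulated genes rose in 5 of 10 cases at 6 d and fell in 0 (7 and 0 adjusted over the list alone; adjusted p = 8.3e-06, and adjusted p = 0.22 with an estimated correlation). Heat shock genes fell in 6 of 8 cases at 8 d and rose in 0, also adjusted over the list alone (adjusted p = 2.73e-06, and adjusted p = 0.187 with an estimated correlation), with Hspb1 at −1.58 ± 0.36.

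The counts were 510 genes at 6 d, 352 higher and 158 lower, and 478 at 8 d, 310 higher and 168 lower. At least 2-fold changes numbered 106 higher and 32 lower at 6 d, and 83 higher and 36 lower at 8 d. Quantile normalization gave 332 higher and 375 lower at 6 d, and 347 higher and 329 lower at 8 d. Array weights gave 986 and 816 genes.

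At 16 d the livers still differed from control, in genes of lipid metabolism and in others. Cyp4a14 was at −7.20 ± 0.54 (adjusted p = 4.07e-13), with 5.95 ± 1.30 (SD, n = 5) against 13.16 ± 0.24. Vnn1 was at −3.55 ± 0.44 and Acot3 at −2.31 ± 0.52. Thrsp was 4.09 ± 0.47, Fdps 3.44 ± 0.38 and Fasn 2.39 ± 0.29 higher. Against 1 h over all probe sets, Thrsp and Fdps were at 3.78 and 3.63 at 16 d, and at 2.50 and 1.77 as the mean of their probe sets. Igfbp1 and Egr1 stood 4.91 ± 0.49 and 4.32 ± 0.56 above control, the latter with a spread of 1.70 (SD, n = 5) between arrays. Cxcl1 was 4.24 ± 0.68 higher, at 9.92 ± 1.91 (SD, n = 5).

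Cholesterol synthesis genes rose in 9 of 10 cases at 16 d and fell in 0, also adjusted over the list alone (adjusted p = 1.91e-19, and adjusted p = 0.0189 with an estimated correlation). Fatty acid synthesis genes counted 7 of 14 higher and 0 lower (9 and 0 adjusted over the list alone; adjusted p = 3.42e-11, and adjusted p = 0.0197 with an estimated correlation). Fatty acid oxidation and fasting genes had 7 of 10 members lower and 1 higher, the same adjusted over the list alone (adjusted p = 1.08e-10, and adjusted p = 0.0573 with an estimated correlation). Heat shock genes had 4 of 8 members lower and 0 higher (7 and 0 adjusted over the list alone), with Hspb1 at −1.77 and Hsph1 at −1.49; the list had adjusted p = 6.23e-07 and adjusted p = 0.149 with an estimated correlation. Proteasome subunits had 4 of 15 members lower and 0 higher (9 and 0 adjusted over the list alone), with Psmd4 at −0.68 (adjusted p = 2.26e-06 for the list, and adjusted p = 0.333 with an estimated correlation).

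At 16 d 398 genes were called, 198 higher and 200 lower, with 77 and 39 changed at least 2-fold. Array weights gave 780 genes, and the fit of the compared groups alone gave 213.

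**Figure D1:**
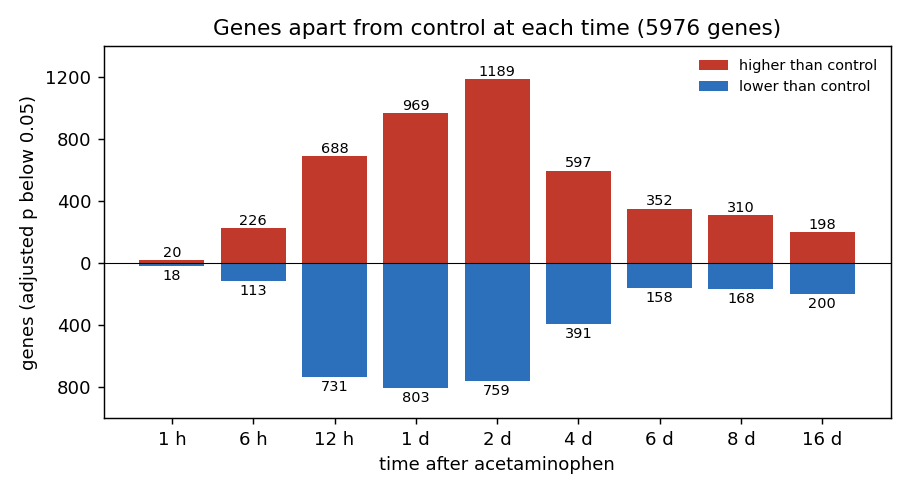
Number of genes above (upward bars) and below (downward bars) control at each time at an adjusted p under 0.05, with the number printed at each bar. The bars hold 38 genes at 1 h, 1772 at 1 d, 1948 at 2 d and 398 at 16 d, and with ribosomal centring the counts were 3617 at 1 d and 3546 at 2 d.

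Across the whole course, 3259 of 5976 genes (54.5%) differed from control by the F test over all 9 times. The largest difference lay at 2 d for 1022 of these genes, 757 of them higher, at 1 d for 724, at 12 h for 552 and at 16 d for 100. The sequence of group medians put immediate early genes first (3.09 at 6 h), heat shock proteins next (1.45 at 12 h), DNA replication, mitosis and matrix genes at 2 d (2.18, 2.23 and 2.40) and cholesterol synthesis at 4 d (2.96). Egr1 and Igfbp1 were above control at each of the 9 times. For Egr1 the control mean was 6.77, and the other group means lay between 9.71 (6 d) and 12.63 (6 h). Starving and vehicle are not stated for the control mice. For these genes a trait of the control livers therefore cannot be separated from a response to the drug. Of 46 lists tested, the number called at the 9 times was 7, 14, 19, 21, 19, 13, 15, 11 and 10 in order of time, and 3, 5, 2, 3, 4, 3, 2, 3 and 3 of these with an estimated correlation. Cell type lists that were not called against control at any of the 9 times included neutrophil markers (8 genes, smallest adjusted p = 0.0629), cholangiocyte and progenitor markers (6 genes, 0.528), stellate cell markers (5 genes, 0.103), B cell markers (6 genes, 0.135) and Kupffer cell markers (3 genes, 0.0514). Circadian clock genes (11 genes, 0.0948), fetal liver genes (5 genes, 0.217), periportal hepatocyte genes (7 genes, 0.118) and female-biased genes (6 genes, 0.347) were not called either. The same held for markers of pancreas (3 genes, 0.0581), skeletal muscle (3 genes, 0.41) and adipose tissue (3 genes, 0.195). For the clock genes a test of shared direction says little, since members moved both ways. At 1 d Nfil3 and Wee1 were higher than control, and Dbp, Per2, Per3 and Usp2 were lower. These 6 of 11 genes (54.5%) compare with 29.6% of other genes called at 1 d (Fisher's p = 0.095).

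**Figure D2:**
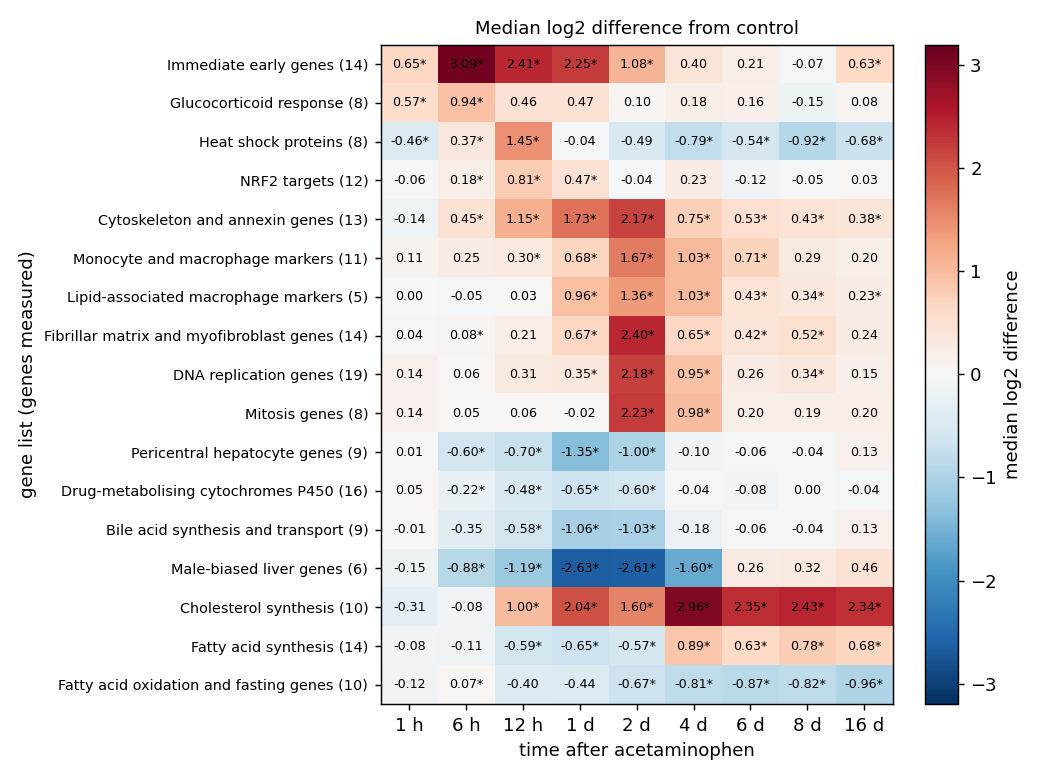
Median log2 difference from control of 17 gene lists (vertical axis, with the number of genes measured) at 9 times after the dose (horizontal axis), with an asterisk where the list was called at the preset correlation. Immediate early genes reach 3.09 at 6 h, matrix genes 2.40 at 2 d and cholesterol synthesis genes 2.96 at 4 d.

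**Figure D3:**
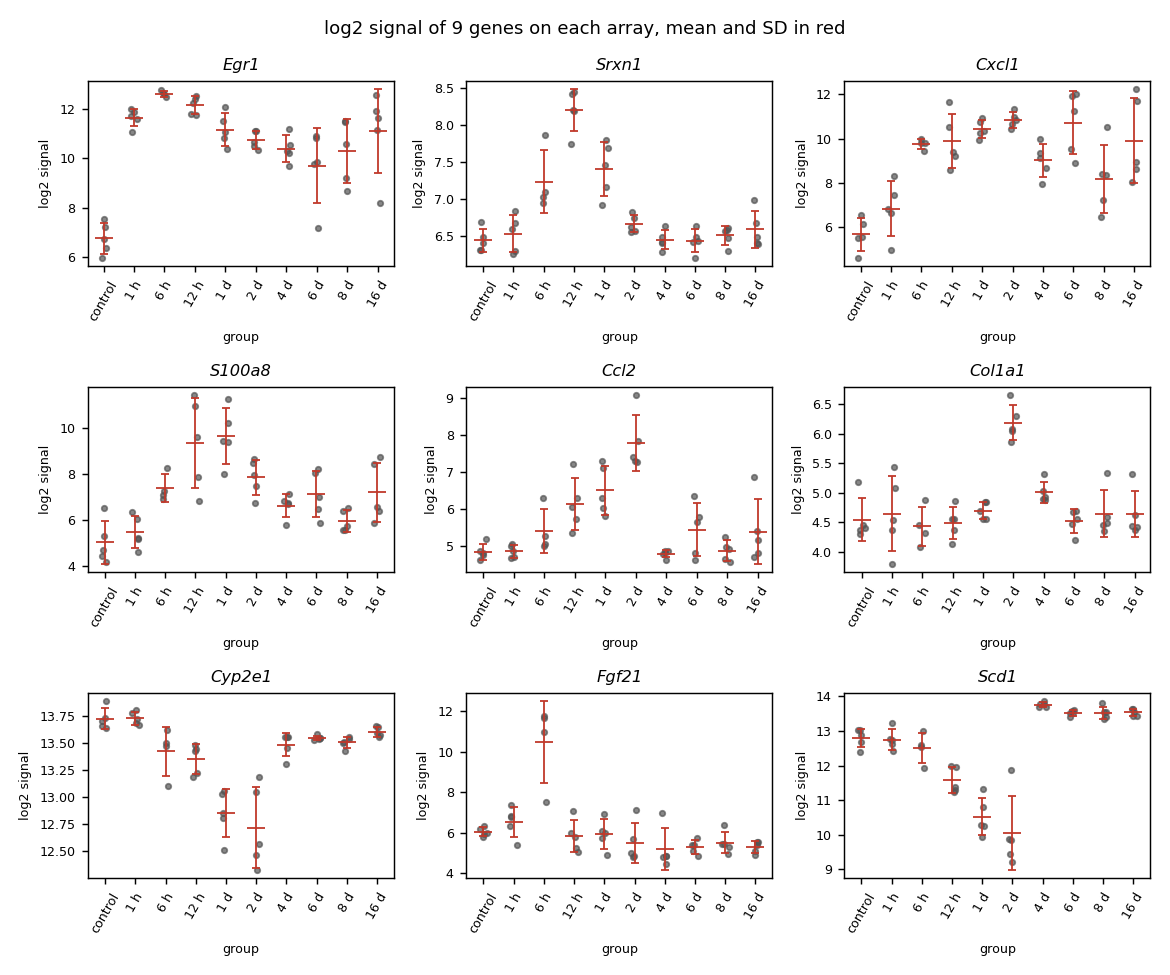
Log2 signal of 9 panel genes in control and at 9 times after the dose, with a point for each array and the group mean ± SD as a bar. Fgf21 peaks at 6 h (10.47 ± 2.00), Srxn1 at 12 h (8.19 ± 0.28) and Ccl2 at 2 d (7.77 ± 0.76), and Scd1 passes from 10.05 ± 1.06 at 2 d to 13.76 ± 0.07 at 4 d.

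Neighbouring times were compared directly, without reference to the control means. From 1 h to 6 h the ATF4 stress response list rose in 3 of 9 cases and fell in 0 (4 and 1 adjusted over the list alone; adjusted p = 0.00042, and adjusted p = 0.0135 with an estimated correlation). Immediate early genes rose in 5 of 14 cases and fell in 0 (7 and 0 adjusted over the list alone; adjusted p = 1.74e-09, and adjusted p = 0.109 with an estimated correlation). Among single genes, Klf6 was 4.53 ± 0.56, Fgf21 3.92 ± 0.55 and Maff 3.88 ± 0.35 higher at 6 h, and Tsc22d3, a glucocorticoid-induced leucine zipper gene, at −1.50 ± 0.28. Of the 254 genes called, 199 were higher and 55 lower at 6 h. Without 6 h replicate 5 the count was 136, and with array weights 817. The split was 173 and 130 with ribosomal centring and 206 and 210 after quantile normalization. From 6 h to 12 h Mmp13, a collagenase, rose by 4.49 ± 0.43, Chil3 by 4.23 ± 0.49 and the cornified envelope gene Lce1f by 3.96 ± 0.24, while Fgf21 dropped back by −4.64 ± 0.55. Of 554 genes 263 were higher and 291 lower, against 215 and 725 with ribosomal centring, which shifted the median of all genes by −0.10. The count was 305, 332, 333 or 356 without 6 h replicate 2, 4 or 5 or 12 h replicate 3, 223 in the fit of the compared groups, 1032 with array weights and 845 after quantile normalization.

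From 12 h to 1 d the heat shock genes came down together while Anxa2 and matrix genes rose. Heat shock genes fell in 7 of 8 cases and rose in 0, also adjusted over the list alone (adjusted p = 4.93e-17, and adjusted p = 0.0135 with an estimated correlation), with Hsph1 at −2.0 ± 0.32 and Bag3 at −2.0 ± 0.31. Anxa2 rose by 2.45 ± 0.30, and Tnfaip6, a hyaluronan-binding protein induced by inflammation, was at −2.67 ± 0.43. Fibrillar matrix genes rose in 6 of 14 cases and fell in 0 (7 and 0 adjusted over the list alone; adjusted p = 2.25e-06, and adjusted p = 0.141 with an estimated correlation). Neutrophil markers were not called from 12 h to 1 d (0 of 8 genes, also adjusted over the list alone, list test adjusted p = 0.502). That list was called higher from 6 h to 12 h, lower from 1 d to 2 d and higher from 8 d to 16 d. Those list tests gave adjusted p = 0.0384, 0.0387 and 0.00601, with 0, 1 and 0 members called (1, 0 and 1 adjusted over the list alone). All 3 calls were lost with an estimated correlation (adjusted p = 0.505, 0.505 and 0.319). Of 304 genes 193 were higher and 111 lower at 1 d. The count depends on the fit, with 39 genes when only the compared groups were fitted, 502 after quantile normalization, 474 without the 3 narrow arrays and 172 without 1 d replicate 4. Ribosomal centring, with a shift of −0.16, gave 95 and 365.

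From 1 d to 2 d cell cycle genes rose, and matrix genes rose further. Col1a2 rose by 3.92 ± 0.26, Cpe, carboxypeptidase E, by 4.13 ± 0.42 and Pclaf, a partner of the replication clamp, by 3.82 ± 0.26. The epidermal differentiation genes Sprr2i and Lce1f were at −2.75 ± 0.22 and −2.71 ± 0.23. DNA replication genes rose in 18 of 19 cases (19 adjusted over the list alone) with adjusted p = 1.74e-27 and adjusted p = 0.00867 with an estimated correlation. Mitosis genes rose in 7 of 8 cases, also adjusted over the list alone (adjusted p = 1.46e-12, and adjusted p = 0.0194 with an estimated correlation), and matrix genes in 9 of 14 (10 adjusted over the list alone; adjusted p = 1.39e-13, and adjusted p = 0.0135 with an estimated correlation). None of the 3 lists had a member that fell. Of 847 genes 628 were higher and 219 lower, against 590 and 486 after quantile normalization.

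From 2 d to 4 d fatty acid synthesis genes rose, and cytoskeletal and most matrix genes fell. Thrsp rose by 5.26 ± 0.47, Elovl6, a fatty acid elongase, by 3.79 ± 0.30 and Scd1 by 3.71 ± 0.27. Acta2 was at −3.55 ± 0.24, on the marked probe set, Chil3 at −3.86 ± 0.46 and S100a6 at −3.44 ± 0.45. Fatty acid synthesis genes rose in 13 of 14 cases and fell in 0, the same adjusted over the list alone (adjusted p = 7.14e-23, and adjusted p = 0.00171 with an estimated correlation). Cytoskeleton and annexin genes fell in 13 of 13 cases, also adjusted over the list alone (adjusted p = 2.79e-15, and adjusted p = 0.0135 with an estimated correlation). Fibrillar matrix genes fell in 11 of 14 cases and rose in 2 (12 and 2 adjusted over the list alone; adjusted p = 4.36e-11, and adjusted p = 0.0308 with an estimated correlation). Monocyte and macrophage markers fell in 6 of 11 cases and rose in 0, the same adjusted over the list alone. Their list test gave adjusted p = 0.0138, and adjusted p = 0.569 with an estimated correlation. Pericentral hepatocyte genes rose in 6 of 9 cases and fell in 0, again the same adjusted over the list alone (adjusted p = 2.12e-08, and adjusted p = 0.0414 with an estimated correlation). Cytochromes P450 rose in 10 of 16 cases and fell in 0 (10 and 1 adjusted over the list alone; adjusted p = 2.75e-07, and adjusted p = 0.0382 with an estimated correlation). Of 1150 genes 345 were higher and 805 lower at 4 d. Ribosomal centring shifted the median of all genes by 0.28 and gave 2378 higher and 353 lower, so the direction of the majority depends on this choice, quantile normalization gave 569 and 707, and array weights called 1779 genes.

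From 4 d to 6 d male-biased liver genes recovered and replication genes declined. Male-biased genes rose in 4 of 6 cases and fell in 0 (5 and 0 adjusted over the list alone; adjusted p = 3.49e-12, and adjusted p = 0.00558 with an estimated correlation), with Elovl3 at 3.37 ± 0.43. Serpina12, the adipokine vaspin, rose by 3.47 ± 0.37 and Ugt2b38, a glucuronosyltransferase, by 3.33 ± 0.46. DNA replication genes fell in 8 of 19 cases and rose in 0 (16 and 0 adjusted over the list alone; adjusted p = 1.06e-22, and adjusted p = 0.0135 with an estimated correlation). Afp was at −2.57 ± 0.32 and Cpe at −3.15 ± 0.42. Of 142 genes 49 were higher and 93 lower at 6 d. The count was 591 with array weights, 379 in the fit of the compared groups, 228 without the 3 narrow arrays and 225 after quantile normalization. Between 6 d and 8 d and between 8 d and 16 d limma called 0 genes, with 146 and 328 genes at an unadjusted p under 0.05 where 298.8 would be expected by chance, and with array weights 8 genes were called from 6 d to 8 d. The glucocorticoid list had a median of −0.60 from 6 d to 8 d, with 0 of 8 members called (3 lower adjusted over the list alone; adjusted p = 1.06e-05, and adjusted p = 0.0103 with an estimated correlation), and of 0.34 from 8 d to 16 d (0 called, also adjusted over the list alone; adjusted p = 0.00343, and adjusted p = 0.0765 with an estimated correlation). Of the other lists called at the preset correlation, 8 from 6 d to 8 d and 4 from 8 d to 16 d, all lost the call with an estimated correlation (adjusted p = 0.0765 to 0.589).

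The 25 arrays with all probe sets allowed 18194 genes to be compared with the 1 h group, a reference that itself carries the early response. At 12 h Hspa1a, the inducible 70-kDa heat shock protein, was 7.12 ± 0.62 above 1 h (adjusted p = 3.06e-08). Heme oxygenase Hmox1 was 2.40 ± 0.45 higher, Gclc, the catalytic subunit of glutamate-cysteine ligase, 1.92 ± 0.24 and Myc 3.48 ± 0.58. The glutamate transporter Slc1a2 and glutamine synthetase Glul, markers of the hepatocytes next to the central vein, were at −4.38 ± 0.22 (adjusted p = 5.08e-12; −1.75 as the mean of the Slc1a2 probe sets) and −2.47 ± 0.18. Lcn2, the acute phase protein lipocalin 2, was 3.74 ± 0.54 higher. Heat shock genes were higher in 11 of 12 cases and lower in 0, also adjusted over the list alone (adjusted p = 2.12e-21, and adjusted p = 0.0195 with an estimated correlation). Ribosome biogenesis genes were higher in 18 of 22 cases and lower in 0 (20 and 0 adjusted over the list alone), with Nop58 at 1.67 ± 0.29 (adjusted p = 9.36e-21, and adjusted p = 0.0838 with an estimated correlation). NRF2 targets counted 14 of 26 higher and 2 lower (16 and 2 adjusted over the list alone; adjusted p = 7.49e-13, and adjusted p = 0.0866 with an estimated correlation).

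At 1 d and 2 d against 1 h the larger set added cell cycle, macrophage and pericentral genes. Glul was at −2.98 at 1 d and −3.11 ± 0.18 at 2 d, Slc1a2 at −4.63 and −4.76 ± 0.22 (−1.87 and −2.03 as the mean of its probe sets), and Cyp1a2 at −2.50 at 1 d. Cyp8b1, a sterol hydroxylase of bile acid synthesis, was at −3.27 ± 0.30 at 1 d. Mki67 and Top2a, expressed in dividing cells, were 3.35 ± 0.26 and 2.99 ± 0.27 higher at 2 d, with 0.96 for Top2a as the mean of its probe sets. The macrophage glycoproteins Cd68 and Gpnmb were 3.09 ± 0.22 and 2.83 ± 0.17 higher at 2 d (1.64 for the mean of the Gpnmb probe sets), the elastase Mmp12 4.04 ± 0.38 and Timp1, an inhibitor of matrix proteases, 2.90 ± 0.33. Clec4f, a lectin of Kupffer cells, was at −0.67 ± 0.16 at 1 d (adjusted p = 0.00413; −1.05 with ribosomal centring) and 0.01 at 2 d, and not called at 2 d. Alb, albumin, was not called at 2 d, but its signal of 14.30 lay at the top of the signal range, so that no stability can be read from it. Acta2 was 4.06 higher at 2 d, and −0.01 on its probe set without a cross-hybridisation mark.

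Pericentral genes were lower in 17 of 20 cases at 1 d and higher in 0 (19 and 0 adjusted over the list alone; adjusted p = 1.81e-14, and adjusted p = 0.0605 with an estimated correlation). At 2 d mitosis genes were higher in 22 of 26 cases and lower in 0 (23 and 1 adjusted over the list alone; adjusted p = 2.52e-20, and adjusted p = 0.105 with an estimated correlation). Monocyte and macrophage markers were higher in 19 of 21 cases and lower in 0 (20 and 0 adjusted over the list alone; adjusted p = 5.46e-16, and adjusted p = 0.0925 with an estimated correlation). Lipid-associated macrophage markers were higher in 10 of 12 cases and lower in 0, also adjusted over the list alone (adjusted p = 1.8e-12, and adjusted p = 0.0195 with an estimated correlation). Fibrillar matrix genes were higher in 18 of 19 cases and lower in 0, the same adjusted over the list alone (adjusted p = 1.44e-20, and adjusted p = 0.0195 with an estimated correlation), with Col3a1 at 4.60 ± 0.39.

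At 16 d no difference from 1 h was called for mitosis genes (0 of 26, also adjusted over the list alone; adjusted p = 0.0938, and adjusted p = 0.759 with an estimated correlation) or pericentral genes (0 of 20, also adjusted over the list alone; adjusted p = 0.119, and adjusted p = 0.658 with an estimated correlation), with Mki67 at 0.22 and Glul at 0.15. Cyp4a14 was at −7.02 ± 0.47, Srebf1, a regulator of lipid synthesis, at 2.31 ± 0.34, and squalene epoxidase Sqle at 3.10. Fkbp5, a glucocorticoid-induced co-chaperone, was at −2.27 ± 0.23 (−1.47 as the mean of its probe sets). Cholesterol synthesis genes were higher in 16 of 19 cases and lower in 0 (17 and 0 adjusted over the list alone; adjusted p = 9.41e-39, and adjusted p = 0.025 with an estimated correlation). Fatty acid synthesis genes were higher in 13 of 18 cases and lower in 0 (15 and 0 adjusted over the list alone; adjusted p = 1.16e-27, and adjusted p = 0.0195 with an estimated correlation). Fatty acid oxidation and fasting genes were lower in 9 of 19 cases and higher in 0 (16 and 0 adjusted over the list alone; adjusted p = 8.18e-23, and adjusted p = 0.0838 with an estimated correlation).

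Against 1 h, 1509 genes were higher and 1868 lower at 12 h, 2119 and 2120 at 1 d, 2696 and 2421 at 2 d, and 266 and 240 at 16 d. Ribosomal centring shifted the median of all genes by −0.24, −0.38 and −0.33 at 12 h, 1 d and 2 d and gave 982 and 8617, 957 and 11749, and 1507 and 10571. At 16 d the count of 506 became 327 without 1 h replicate 4, 324 without 1 h replicate 5, 2131 with array weights and 942 after quantile normalization. The log2 difference between the 3' and 5' control probe sets of Actb, a sign of RNA integrity that is larger in degraded RNA, was 0.65 ± 0.08 (SD, n = 5) at 1 h. It was 0.37 ± 0.04 at 12 h, 0.42 ± 0.05 at 1 d, 0.38 ± 0.09 at 2 d (each exact two-sided permutation p = 0.00794, adjusted p = 0.0212) and 0.55 ± 0.10 at 16 d (exact p = 0.0952, adjusted p = 0.152). That of Gapdh was −0.10 at 1 h and gave adjusted p = 0.0794 to 0.881 in the same exact tests, 8 in all. The 12 h, 1 d and 2 d gene groups described against 1 h thus moved together with a lower Actb difference.

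**Figure D4:**
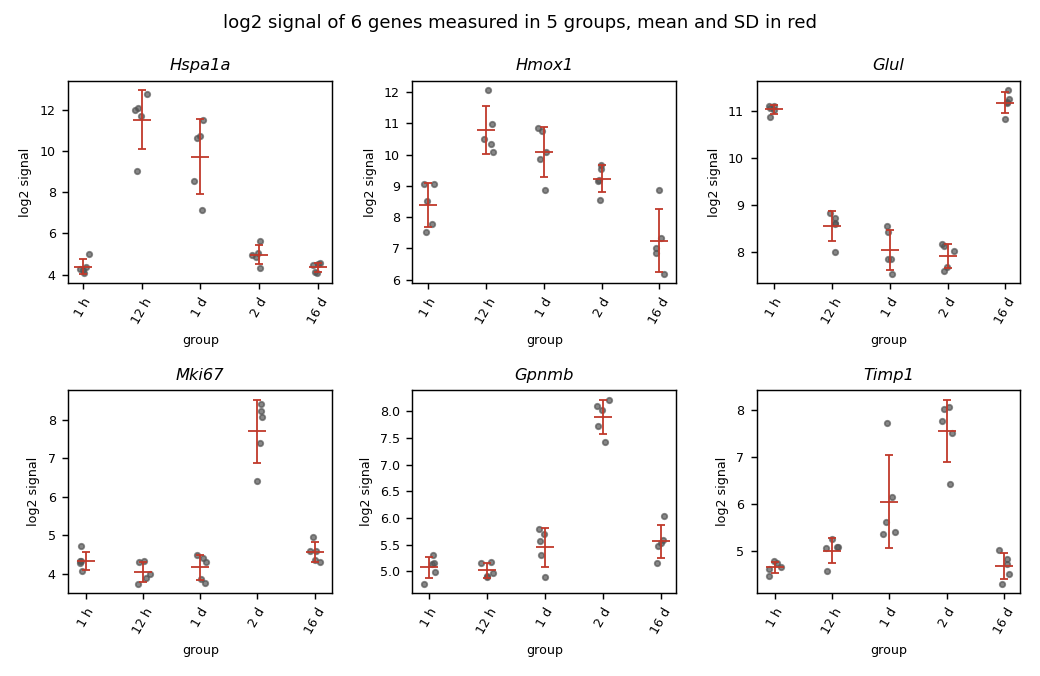
Log2 signal of 6 panel genes on the 25 arrays with all probe sets, in 5 groups, with a point for each array and the group mean ± SD as a bar. Hspa1a is highest at 12 h (7.12 above 1 h), Mki67 and Gpnmb at 2 d (3.35 and 2.83 above 1 h), and Glul is at −3.11 at 2 d and 0.15 at 16 d.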

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

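The tests of the feeding state of the controls, of the time of day for the late lipid genes, and of the 3 arrays of narrow range were chosen after the result was seen. The gap of the highest or lowest array to its nearest neighbour, as a share of the group's range, passed Dixon's 95% limit in 25 of 329 tests, where chance gives about 1 in 20 groups, or 16.45. Many of these cases lie on a few arrays.

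At 4 d, replicate 1 stood apart in metabolic and stress genes. Fgf21 was at 7.0 against a mean of 4.75 on the other 4 arrays (ratio of gap to range 0.842), Cdkn1a at 8.45 against 7.22 (0.770), Dbp at 5.72 against 9.06 (0.809) and Pck1, an enzyme of gluconeogenesis, at 10.46 against 12.48 (0.946). The mean of the fatty acid synthesis list was 11.09 against 10.32 (0.75) and that of cytoskeleton and annexin genes 9.74 against 9.06 (0.803). A mislabelled array is argued against, since its own group ranked 1 by distance (0.327, next 8 d with 0.408). Collection at another time of day stays open. Of 5 other clock genes, 5 lay beyond the other 4 arrays, with Per2, Per3, Usp2 and Nr1d2 below and Nfil3 above. Per2 (6.15, lowest other 6.27) and Nfil3 (8.34, highest other 8.25) did so narrowly. At 1 d against control Nfil3 was also higher and Dbp, Per2, Per3 and Usp2 were lower, while Nr1d2 was not called. The clock genes alone thus cannot tell a time of day from a difference in injury. A difference in injury or in feeding between animals was not tested.

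The SD of the values was 2.25 on control replicate 3 (ratio 0.900), 2.26 on 1 h replicate 3 (0.762) and 2.26 on 16 d replicate 4 (0.921), against 2.44, 2.43 and 2.45 on the other arrays of these groups. Their deviations from their group means resembled each other across groups (correlation 0.816, 0.799 and 0.825, against at most 0.618 for any other pair). On these arrays 2057 genes with mean signal between 6 and 9 were lowered by a median of −0.56, and 2057 genes below 5 were raised by 0.20. RNA degradation is argued against as the cause on 1 h replicate 3 and 16 d replicate 4. On these, 0 of 4 differences between 3' and 5' probe sets lay above the rest of the group. Control replicate 3 held no values for those probe sets, so degradation was not tested there. A large amount of RNA of the same other tissue is argued against on all 3 narrow arrays. Of the 5 genes raised at least 2-fold on all 3 (Cnr1, Cntn3, Insrr, Svs5 and Tspan8), 0 reached a signal of 7.86, above which the highest 25% of all values lie. A small admixture, or a different tissue on each array, could not be seen in this test. A shared step of hybridisation or labelling stays open, as no batch is given in the labels, and no biological explanation was tested.

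Several single genes were apart on the same arrays. Col1a1 was high on control replicate 3 (5.19 against 4.38, ratio 0.825) and on 16 d replicate 4 (5.32 against 4.47, 0.737), and Saa1, serum amyloid A, on 1 h replicate 3 (13.1 against 10.7, 0.934). Nqo1 (4.79 against 5.70, 0.932) and the cholesterol synthesis list (9.0 against 9.57, 0.916) were low on 16 d replicate 4. Col1a1 was also high on 8 d replicate 3 (5.34 against 4.47, 0.765).

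At 6 h, replicate 1 had the highest Srxn1 (7.86 against 7.02, ratio 0.831), the lowest Pck1 (12.49 against 12.67, 0.907) and the lowest mean of the glucocorticoid list (0.897). At 12 h, replicate 2 was low in ER chaperones (10.29 against 10.91, 0.805) and acute phase proteins (10.62 against 11.47, 0.831) and high in ribosome biogenesis genes (8.56 against 8.20, 0.812). Replicate 1 of 2 d had a high Scd1 (11.88 against 9.59, 0.751), and replicate 2 of 2 d a low DNA replication list (6.21 against 7.63, 0.719). Male-biased genes were low on 4 d replicate 5 (8.03 against 8.92, 0.836), and heat shock genes were high on 6 d replicate 3 (9.77 against 9.16, 0.794).

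Some gene lists were called higher than control at one time and lower at another at the preset correlation. The pairs of times below were picked for that, so a test of their difference would restate the choice and no p is given. Of these calls, that of fatty acid synthesis genes at 16 d was kept with an estimated correlation (adjusted p = 0.0197) and the others were lost (adjusted p = 0.0573 to 0.617 with an estimated correlation). The values are medians, over the genes of a list, of the difference between the 2 times. Fatty acid oxidation and fasting genes were 1.59 higher at 6 h than at 16 d, and fatty acid synthesis genes 1.59 higher at 16 d than at 1 d. Heat shock genes were 2.43 and ribosome biogenesis genes 0.56 higher at 12 h than at 16 d. Conjugation genes were 0.87 higher at 4 d than at 1 d, secreted plasma proteins 0.33 higher at 6 d than at 1 d, and ER chaperones 0.42 higher at 6 d than at 1 h.

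The late difference from control, with lipid synthesis genes higher and fasting genes lower, raises the question of the reference. Counting fasting genes with their sign turned, the median change of the 3 lists was −0.081 at 1 h and 0.52 at 2 d. It was 1.48 at 4 d, and 1.17, 1.29 and 1.22 at 6 d, 8 d and 16 d. The question of the reference thus holds for 4 d too, although fatty acid synthesis genes also rose from 2 d to 4 d without reference to control. By these lists the controls lay near the 1 h mice, starved overnight before the dose, as controls in a fasted state would. Other genes linked to fasting did differ from control at 1 h, with gluconeogenesis and glucocorticoid-responsive genes higher (adjusted p = 0.00033 for each with an estimated correlation), so the comparison with 1 h does not settle whether the controls were fasted. The feeding state of the control mice stays open, and a lasting effect of the injury cannot be separated from it here. For 6 d, 8 d and 16 d the 3 narrow arrays are argued against, since 9 of 9 list calls were kept without them. For the time of day the test was undecided, as clock genes were called more often than other genes at 1 of the 3 times, 16 d (4 of 11 genes, Fisher's p = 0.00439; 8 d, 3 of 11, p = 0.0517; 6 d, 1 of 11, p = 1).

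Probe sets without a single gene symbol were not used in the comparisons. Of 10092 such probe sets on the complete arrays, 450 were higher and 1227 lower at 2 d than at 1 h, and 35 of them changed at least 4-fold, 29 up and 6 down.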

How the results depend on the processing

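Quantile normalization, the fits without the 3 narrow arrays or without a pair of arrays with a shared deviation, and the comparisons with 1 h over all probe sets were tests chosen after the data were seen. No called gene list was called in the opposite direction under any of the alternatives run. Dim genes were those whose highest group mean did not exceed the median of all values. Without them 35 list calls were lost and 192 kept, while 623 values of named genes kept direction and side of the threshold.

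Array weights raised the counts of genes to 131 at 1 h, 759 at 6 h, 1529 at 4 d, 986 at 6 d, 816 at 8 d and 780 at 16 d against control, to 817 from 1 h to 6 h, 1032 from 6 h to 12 h, 1779 from 2 d to 4 d, 591 from 4 d to 6 d and 8 from 6 d to 8 d, and to 2131 at 16 d against 1 h. Quantile normalization gave 556 at 6 h, 416 from 1 h to 6 h, 845 from 6 h to 12 h, 502 from 12 h to 1 d, 225 from 4 d to 6 d and 942 at 16 d against 1 h. Fitting only the compared groups gave 805 at 12 h, 1135 at 1 d, 213 at 16 d, 223 from 6 h to 12 h, 39 from 12 h to 1 d and 379 from 4 d to 6 d. It gave 11 lists at 1 h and 16 at 16 d, adjusted over all lists and times. Centring on ribosomal protein genes gave 3617 at 1 d, 3546 at 2 d, 940 from 6 h to 12 h, 460 from 12 h to 1 d and 2731 from 2 d to 4 d, and against 1 h 9599, 12706 and 12078 at 12 h, 1 d and 2 d. Without the 3 narrow arrays 474 genes were called from 12 h to 1 d and 228 from 4 d to 6 d. Without dim genes 12 lists were called at 12 h, where fewer genes were tested. For the other changes the cause was not tested.

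With an estimated correlation 3, 5, 2, 3, 4, 3, 2, 3 and 3 lists were called against control in order of time, and 1, 1, 3 and 2 against 1 h, as 193 list calls were lost and 35 kept. Leaving out probe sets open to cross-hybridisation turned Trem2 at 2 d to −0.0052, and Acta2 against 1 h to −0.042 at 12 h, −0.10 at 1 d and −0.013 at 2 d, where another probe set then stood for the gene. Ribosomal centring turned Alb against 1 h to −0.22, −0.33 and −0.22 at 12 h, 1 d and 2 d, which follows from the shift of all genes (−0.24, −0.38 and −0.33) and tells nothing of Alb itself.

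Leaving out each array in turn gave 26 to 79 genes at 1 h, 223 to 354 at 6 h, 1181 to 1424 at 12 h, 1574 to 1736 at 1 d, 1590 to 1978 at 2 d, 841 to 1044 at 4 d, 408 to 478 at 6 d, 356 to 532 at 8 d and 326 to 513 at 16 d. From 1 h to 6 h it gave 136 to 253, from 6 h to 12 h 305 to 706, from 12 h to 1 d 172 to 314, and at 16 d against 1 h 324 to 703. The lists called ranged from 5 to 10 at 1 h and from 8 to 14 at 16 d. The highest 1 h count came without control replicate 3, and the lowest counts without 6 h replicate 5 (at 6 h, and from 1 h to 6 h), 6 h replicate 2 (from 6 h to 12 h), 1 d replicate 4 (from 12 h to 1 d) and 1 h replicate 5 (at 16 d against 1 h). List calls numbered 2162 kept and 104 lost. Of the values for single named genes, 6020 kept direction and side of the threshold when 1 array was left out, 169 lost the call and 22 gained one.

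The replicate number as a block gave 44, 333, 1524, 1893, 2093, 1115, 559, 527 and 438 genes against control in order of time, and 2 list calls were lost. For arrays of the same number in this block the residual correlation averaged 0.0632, with single pairs from −0.533 to 0.816, against an average of −0.0128 for different numbers. Trend and robust variance kept 625 named gene values and gained 1. Without control replicate 2 and 8 d replicate 2, 377 named gene values and 128 list calls were kept, 12 and 1 were lost and 1 gene was gained. This pair (residual correlation 0.588) was not the closest of the pairs of different groups that remain beside those among the narrow arrays, where another reached 0.618. Of the list calls, 14 were lost with array weights, 17 after quantile normalization, 15 without the narrow arrays, 11 with ribosomal centring, 9 without probe sets open to cross-hybridisation, 7 in the fit of the compared groups and 4 with the mean of all probe sets.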

Other observations

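The comparisons with 1 h and their tests were chosen after the data were seen. Several lists had more members among the 18194 genes compared with 1 h. Sinusoidal endothelial markers were higher at 2 d in 9 of 20 cases and lower in 0 (10 and 0 adjusted over the list alone; adjusted p = 0.000636, and adjusted p = 0.386 with an estimated correlation). Urea cycle and amino acid genes were lower in 14 of 16 cases at 1 d and higher in 0, also adjusted over the list alone (adjusted p = 1.19e-09, and adjusted p = 0.172 with an estimated correlation). Bile acid genes were lower in 14 of 18 cases at 1 d and higher in 0 (15 and 0 adjusted over the list alone; adjusted p = 2.5e-10, and adjusted p = 0.0925 with an estimated correlation). At 16 d the glucocorticoid list was lower than at 1 h in 2 of 12 cases (5 adjusted over the list alone; adjusted p = 3.62e-09, and adjusted p = 0.0605 with an estimated correlation).

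For the genes that differed from control, chance as the source of the counts was tested by 100 splits of the arrays of both groups, in a fit of these groups alone. No other split reached the real count at 1 h (39 genes, highest other split 2), 6 h (239, 126), 12 h (805, 9), 1 d (1135, 107), 2 d (1402, 0), 4 d (745, 73), 6 d (524, 1), 8 d (324, 0) and 16 d (213, 3). In each case 1 of the 100 splits, the real one, was as large, which argues against chance as the source. The same held from 1 h to 6 h (203, 51), 6 h to 12 h (223, 34), 1 d to 2 d (576, 173), 2 d to 4 d (1301, 136) and 4 d to 6 d (379, 2). From 12 h to 1 d (39, 29) the highest other split came close to the real count, so chance is not excluded there. The splits cannot tell the dose from any other trait that the arrays of a group share. From 6 d to 8 d and from 8 d to 16 d the splits decide nothing, because with a real count of 0 genes all 100 splits are as large (highest other 1). For any time no shuffle of the groups reached the real count (3259, 431). Against 1 h no other split did so at 12 h (2558, 67), 1 d (3571, 553), 2 d (4789, 155) and 16 d (485, 3).

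The number of gene lists called is a weaker measure, since members of a list move together on single arrays. In the splits the lists were adjusted over the contrast alone, so their numbers differ from those of the other fits. At 6 h (18 lists, highest other 17), 12 h (20, 21), 1 d (23, 24) and 16 d (16, 17) few splits reached the real number. As large were 1, 2, 2 and 2 of the 100 splits, the real one included. Other splits came close to the real number or passed it, so chance is not excluded. More splits were as large at 1 h (7, 16), 2 d (22, 25), 4 d (13, 16), 6 d (14, 16) and 8 d (11, 13). There 26, 6, 16, 9 and 9 splits were as large, and chance is not excluded either. Against 1 h, 2 splits were as large at 1 d (32, 32) and 2 at 16 d (22, 23). At 12 h (26, 29) and 2 d (27, 30) 7 and 8 were as large. Chance is not excluded for any of these comparisons with 1 h.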
